A study of Mus musculus with 17 samples.

How the data were processed

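Single-cell RNA profiles of the ileum, the last part of the small intestine, were made from female mice with the 10x Genomics Chromium 3' kit, in which each captured transcript end carries a unique molecular identifier (UMI). Per the labels, 3 samples came from virgin wild-type (WT) females, 11 from WT females at day 7 of lactation and 3 from females at day 7 of lactation without Slc5a4a, the gene of the sugar-binding membrane protein SGLT3a (knockout, KO). The labels do not say that the samples are separate animals, so the p values measure the spread between these samples. The deposited matrices hold raw UMI counts of 32285 genes in the barcodes that the authors' Cell Ranger runs kept as cells. The processing notes of the labels name Cell Ranger 5.0.1 and the mouse genome build GRCm38 for all samples. The file headers instead name Cell Ranger 4.0.0 for the 3 virgin samples and lactating WT 7 to 11 (8 samples), and 5.0.1 for lactating WT 1 to 6 and the 3 KO samples (9 samples). Total UMIs per sample, over the deposited barcodes, ran from 30.44 to 89.22 M under 4.0.0 and from 12.81 to 19.39 M under 5.0.1, so depth and file version go together.

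Barcodes were kept with at least 1000 UMIs, at least 400 genes and at most 30% mitochondrial UMIs, which left 99672 of 134010. Doublets, barcodes that hold more than 1 cell, were scored in each sample by the share of simulated doublets among the nearest neighbours. The highest scores were removed at a rate of 0.8% per 1000 barcodes (6800 barcodes), which left 92872 cells. Counts per cell were scaled and log-transformed, and 2000 variable genes, ranked within samples, gave 30 principal components. No batch integration was used. A graph of 15 neighbours was divided into 22 clusters with the Leiden method at resolution 1 (igraph 0.11.9, leidenalg 0.10.2, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, figures with matplotlib 3.10.9). Clusters were named from 17 marker lists alone. UMIs were summed per sample and cell class, with at least 20 cells required, so that the sample and not the cell was the replicate. Paneth and enteroendocrine cells were too few in too many samples for tests of single genes.

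Genes were tested in enterocytes, crypt progenitors, goblet cells and all cells summed with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on TMM-normalised sums, after its filter on low counts, in a fit of all 17 samples with the 3 groups as the only term. The tests were two-sided, and Benjamini-Hochberg adjusted p values under 0.05 were called. The SE of a log2 change was derived from the test, as the size of the change over the square root of its F statistic. Values per sample are CPM, the UMIs of a gene per 1e6 UMIs of the class, with that total scaled by the TMM factor of the sample. For 28 gene lists, limma 3.58.1 camera was run with a preset correlation of 0.01 between genes, and again with an estimated correlation. Lists needed at least 5 tested genes, and p values were adjusted over the lists within a class and comparison. Counts of list members are given over all genes and adjusted over the list alone. Class shares and cycling scores were compared with exact permutation tests over all splits, two-sided, with Benjamini-Hochberg adjustment over 10 and 6 tests. Cells were thinned to 1000 UMIs before cycling was scored. Gene positions came from the GRCm38 annotation, which held 32158 of the 32285 identifiers.

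The groups, the filters, the tests, the gene lists, the markers and the rule for named genes were set before the data were examined. In enterocytes and crypt progenitors the rule names up to 8 rises and 8 falls by size of change, among genes with adjusted p under 0.05, a mean of at least 20 CPM in the higher group, and all 3 samples of the smaller group on the same side of the lactating WT median. In goblet cells and in all cells summed it names up to 4 each way. It also names 2 to 4 members of each list described, and always Slc5a4a, Slc5a4b, Slc5a1 and Fgfbp1. Genes known only by clone or model numbers were passed over. The file version was found in the headers afterwards. Fits within samples of 1 version (virgin 1 to 3 with lactating WT 7 to 11, and KO 1 to 3 with lactating WT 1 to 6), a fit with the version as a covariate, and the same naming rule in the fits within a version were therefore chosen after seeing the data.

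The fits were tested on simulated data with 200 changed genes, divided evenly between 2-fold and 4-fold changes. In enterocytes with all samples, 62% of 2-fold and 93% of 4-fold changes were recovered for lactation, and 51% and 87% for the knockout, and 4.3% and 5.5% of the calls were false. Within 1 version these figures were 79% and 96% for lactation and 67% and 95% for the knockout, with 8.4% and 5.8% false. In crypt progenitors with all samples they were 66% and 97% for lactation and 59% and 92% for the knockout, with 4.7% and 4.4% false. Within 1 version they were 84% and 100% for lactation and 71% and 96% for the knockout, with 4.2% and 4.6% false. In a simulation where 1 list of 28 was raised 1.5-fold, camera called that list and 0 others. All these simulations drew each gene independently of the others and left out the file version. In those of single genes, the genes of lowest count were not among the changed ones. The shares of recovered and false calls therefore need not hold in the real data. Alternatives were DESeq2 1.42.0, its size factors inside edgeR, no filter on low counts, 1 surrogate variable (sva 3.50.0), the sample numbers as a block, fits of the compared groups alone, thinned sums, a strict cell filter (2000 UMIs, 1000 genes, 15% mitochondrial), doublets kept, clustering at resolution 0.5 or 2 or on genes centred within samples, fry for lists, and leaving out each sample in turn. Left out of the tests of single genes were genes under the count filter, and Slc5a4a and Slc5a4b in crypt progenitors and goblet cells, where they fell under it.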

Results

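Gene expression was measured in single cells of the ileum of 3 virgin WT samples, 11 lactating WT samples and 3 lactating KO samples of mice at day 7 of lactation, or of virgin females of matched age. Total UMIs over the deposited barcodes, in M (mega), were 89.22, 46.69 and 36.66 M in virgin 1 to 3. They were 17.56, 12.81, 16.63, 13.0, 15.69 and 19.39 M in lactating WT 1 to 6, and 60.23, 53.34, 69.14, 81.23 and 30.44 M in lactating WT 7 to 11. The KO samples held 13.81, 13.93 and 15.02 M. After filtering, the median kept cell held between 2544 and 9178 UMIs, depending on the sample. The 92872 cells comprised 83352 enterocytes, the absorptive cells of the villus, 4733 crypt progenitors, the dividing and stem cells at its base, and 3801 mucus-secreting goblet cells. A further 509 were Paneth cells and 477 enteroendocrine cells. No cluster was named for tuft cells, lymphocytes or any other listed type, so any such cells lie within these classes.

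The 2 file versions separated the lactating WT samples strongly. The labels do not say whether these samples also differ in date, place or cohort, so the difference is not shown to come from the software, and version stands here for whatever sets the 2 sets of samples apart. Within lactating WT alone, 6 samples of version 5.0.1 against 5 of version 4.0.0 differed in 6149 of 10828 enterocyte genes, with 3005 higher and 3144 lower in 5.0.1 (edgeR). In crypt progenitors 4691 of 9514 genes differed and in goblet cells 623 of 6734. The summed CPM of MHC class II genes, which present antigen to T cells, was 1148 ± 428.5 (SD, n = 5) in enterocytes of lactating WT samples of version 4.0.0 and 7378 ± 831 (SD, n = 6) in those of 5.0.1, beside 1744 ± 1046 (SD, n = 3) in virgin samples. The antimicrobial lectins Reg3b and Reg3g, summed, came to 11350 ± 6402 CPM (SD, n = 5) and 114700 ± 27820 CPM (SD, n = 6) in these lactating groups, beside 13150 ± 3395 CPM (SD, n = 3) in virgin samples. UMIs of genes that overlap ribosomal RNA made up 0.051% to 0.217% per sample in version 4.0.0 and 0.407% to 3.953% in 5.0.1, with the highest value in KO 3. All virgin samples are of version 4.0.0 and all KO samples of version 5.0.1. Values from all samples are therefore given beside those within 1 version, which compare the virgin samples with lactating WT 7 to 11, and the KO samples with lactating WT 1 to 6.

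**Figure D1:**
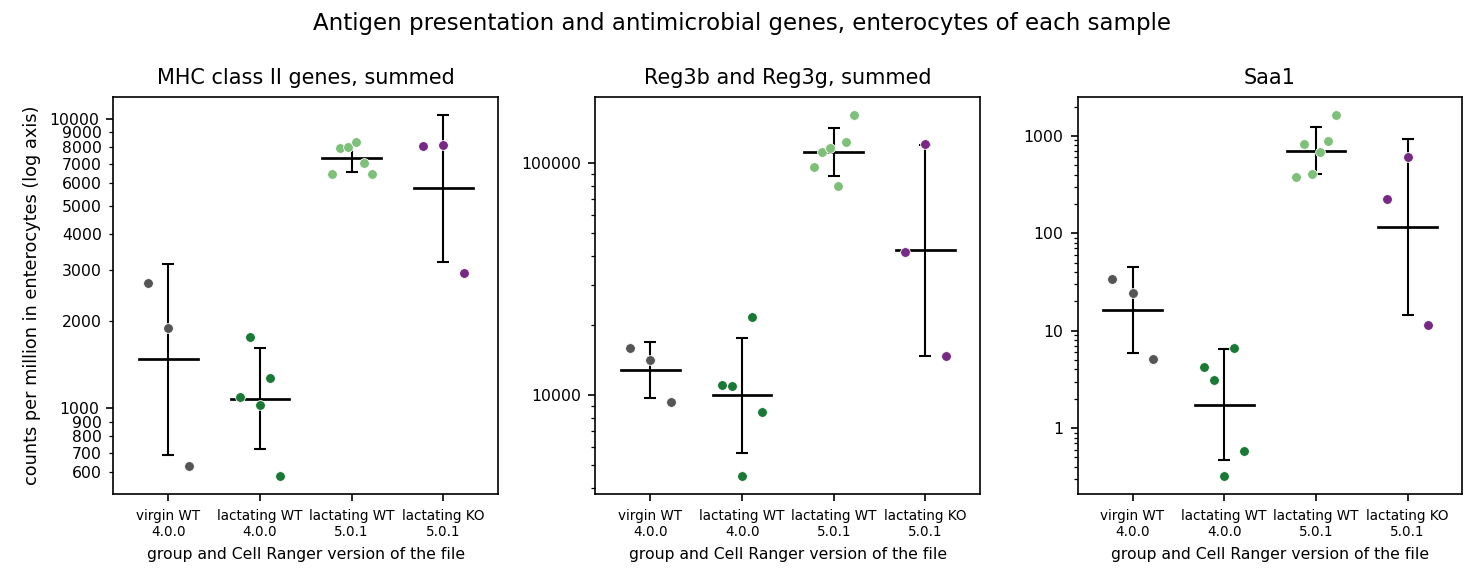
Summed CPM of MHC class II genes, summed CPM of Reg3b and Reg3g, and CPM of Saa1 in enterocytes, on log axes, with 1 point per sample in 4 groups by condition and Cell Ranger version; black lines are geometric means and bars 1 SD of the log10 values either way. The lactating WT samples of version 5.0.1 lie above those of version 4.0.0 in MHC class II genes, with means of 7378 and 1148 CPM.

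The first question was how the ileum differs between lactating and virgin WT females in its cell types. Enterocytes made up 90.27% ± 1.56 (SD, n = 3) of cells in virgin samples, 89.63% ± 3.79 (SD, n = 11) in lactating WT and 89.54% ± 4.85 (SD, n = 3) in lactating KO samples. Crypt progenitors made up 5.16% ± 1.05, 5.10% ± 2.88 and 4.99% ± 4.06, and goblet cells 3.37% ± 0.498, 4.24% ± 1.67 and 4.63% ± 1.66 of the cells in the same groups (SD). Paneth cells made up 0.633%, 0.517% and 0.452%, and enteroendocrine cells 0.564%, 0.508% and 0.390%. None of the 10 differences in share passed the exact permutation test (two-sided; adjusted p = 0.981 for all 10), and isolation of cells can itself set such shares. Enterocytes and crypt progenitors of the file versions lay in different clusters, except those of KO 3. Of its enterocytes 57.71% lay in cluster 16, apart from both versions. That cluster held 0.410% of those of KO 1 and 2, 0.0775% of virgin ones, and 0.053% and 0.0166% of those of lactating WT of versions 4.0.0 and 5.0.1. A further 14.75% of the enterocytes of KO 3 lay in cluster 1, which held 19.67% of those of lactating WT of version 4.0.0. Crypt cluster 13 held 99.29% of virgin and 99.93% of lactating WT crypt cells of version 4.0.0 and 96.33% of those of KO 3. Cluster 18 held 99.82% of those of lactating WT of version 5.0.1 and 98.02% of those of KO 1 and 2. Goblet clusters 12 and 19 held cells of all groups.

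Cycling crypt progenitors were counted as those with a UMI of Mki67 or Top2a, genes of dividing cells, after each cell was thinned to 1000 UMIs. They made up 39.34% ± 1.81 (SD, n = 3) in virgin, 34.88% ± 6.99 (SD, n = 11) in lactating WT and 34.84% ± 12.29 (SD, n = 3) in lactating KO samples. Lactating WT samples of version 4.0.0, the version of the virgin samples, had 38.58% ± 7.57 (SD, n = 5). The difference between lactating and virgin WT did not pass the exact permutation test (two-sided p = 0.308, adjusted p = 0.584), nor did that between KO and lactating WT (p = 0.995, adjusted p = 0.995, exact). Without thinning the shares were 82.44%, 69.04% and 62.01%. In enterocytes, which should lack both genes, 0.329% of cells had such a UMI after thinning, at a mean of the samples' median depths of 3835 UMIs, beside 10120 UMIs in crypt progenitors.

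In enterocytes, the metal-binding or metal-carrying genes S100g, Slc30a10, Slc39a4 and Slc31a1 rose in lactation within 1 file version, while the metallothionein Mt1 fell. The call of Mt1 was lost without virgin 1, virgin 2 or lactating WT 7, 9 or 11 (adjusted p 0.0624 to 0.152). S100g, the calcium-binding protein calbindin-D9k (ENSMUSG00000040808; GRCm38 chromosome X, 162961992 to 162964599), went from 14.8 ± 8.52 CPM (SD, n = 3) in virgin samples to 744 ± 362 CPM (SD, n = 5) in lactating WT samples of the same version, a log2 change of 5.65 ± 0.59 (SE; edgeR adjusted p = 0.00172). The manganese exporter Slc30a10 (ENSMUSG00000026614; chromosome 1, 185454848 to 185468762) rose from 15.5 ± 2.30 to 52.6 ± 4.49 CPM (SD, n = 3 and 5), by 1.77 ± 0.12 on the log2 scale within the version (edgeR adjusted p = 0.00013) and by 2.31 ± 0.32 over all samples (adjusted p = 0.00343). The zinc importer Slc39a4 (ENSMUSG00000063354; chromosome 15, 76612383 to 76617384) rose from 254 ± 37.6 to 825 ± 133 CPM (SD, n = 3 and 5), by 1.71 ± 0.17 within the version (adjusted p = 0.00146) and by 1.42 ± 0.23 over all samples (adjusted p = 0.0127). The copper importer Slc31a1 (ENSMUSG00000066150; chromosome 4, 62360727 to 62391769) rose by 1.08 ± 0.10 (adjusted p = 0.0012) and 0.93 ± 0.14 (adjusted p = 0.00784). S100g did not pass the test over all samples (log2 4.69 ± 1.23, adjusted p = 0.131), where lactating WT samples of version 5.0.1 had 77.5 ± 44.7 CPM (SD, n = 6). Over all samples Slc30a10, Slc39a4 and Slc31a1 each lost the call without virgin 2 and without virgin 3, among 14 named genes that all did so, with adjusted p from 0.0727 to 0.328 and from 0.0612 to 0.35. Of the 14, 9 lost it without virgin 1 (0.0571 to 0.276). Within the version these metal genes kept the call without any single sample. Their highest adjusted p was 0.0189 for S100g, 0.0021 for Slc30a10, and 0.0155 for Slc39a4 and for Slc31a1.

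**Figure D2:**
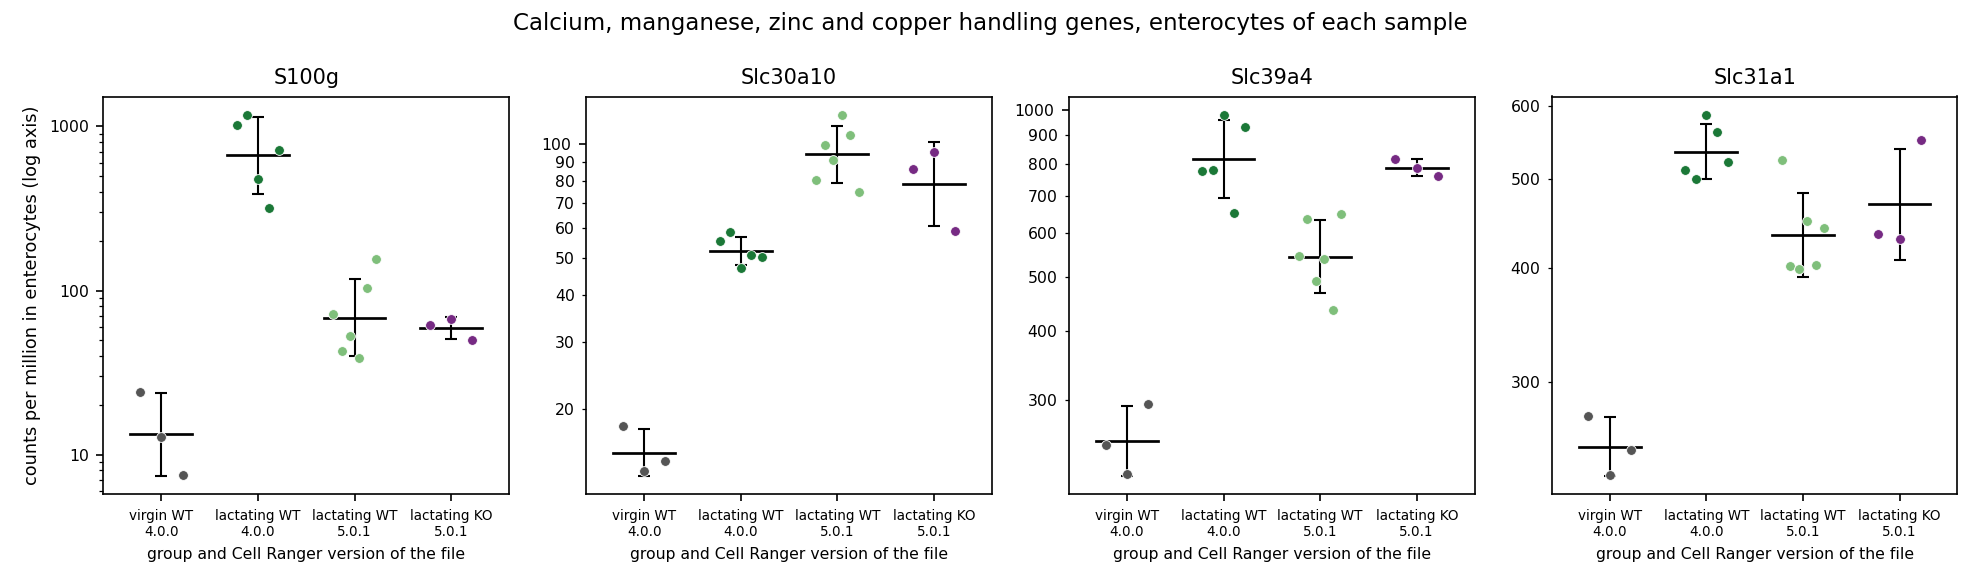
CPM of S100g, Slc30a10, Slc39a4 and Slc31a1 in enterocytes, on log axes, with 1 point per sample in 4 groups by condition and Cell Ranger version; black lines are geometric means and bars 1 SD of the log10 values either way. Slc30a10 averages 15.5 CPM in virgin samples and 52.6 and 95.3 CPM in the lactating WT samples of versions 4.0.0 and 5.0.1.

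Other genes of known function moved in the same enterocytes. Within the version, Angptl4, an inhibitor of lipoprotein lipase (ENSMUSG00000002289), rose by 1.91 ± 0.17 on the log2 scale (SE; adjusted p = 0.000868; over all samples 1.33 ± 0.50, adjusted p = 0.295). Bcl6, a transcriptional repressor (log2 -2.32 ± 0.30, adjusted p = 0.00655; over all samples -2.19 ± 0.39, adjusted p = 0.0189), was lower, and it lost the call within the version with genes centred before clustering (adjusted p = 0.0718). Over all samples the naming rule also gave, among others, Acta1, an actin of skeletal muscle (log2 2.37 ± 0.46), the riboflavin kinase Rfk (0.85 ± 0.17), the riboflavin transporter Slc52a3 (0.79 ± 0.15) and the translation repressor Eif4ebp3 (0.84 ± 0.12) as higher. It gave Gsdmc4, a gasdermin (-2.12 ± 0.40), the cold-induced RNA-binding protein gene Cirbp (-0.52 ± 0.10) and Sowaha (-0.46 ± 0.09) as lower, with adjusted p from 0.00493 to 0.0373 for these 7 genes. Within the version Rfk and Cirbp were not called (adjusted p = 0.0528 and 0.0542). The rule there also gave the heme transporter homologue Flvcr2 (1.56), the peroxisomal thiolase Acaa1b (1.29) and the aquaporin Aqp3 (1.26) as higher. It gave the metallothionein Mt1 (-2.44), Gsdmc2 (-1.45), the cholesterol exporter Abca1 (-1.34), the bile acid-induced hormone Fgf15 (-1.22), the immunoproteasome subunit Psmb8 (-0.94), Naip1 (-0.82) and Kitl (-0.79) as lower. Their adjusted p ran from 0.000868 to 0.0339. Over all samples none of these 10 genes was called, with adjusted p = 0.15 for Flvcr2, 0.0922 for Mt1, 0.0584 for Gsdmc2, 0.0816 for Abca1 and 0.0772 for Fgf15. The log2 changes of Acaa1b, Aqp3, Psmb8, Naip1 and Kitl there were 0.45, 0.48, 1.32, -0.10 and -0.35. Gasdermin C genes are near-identical copies, so their reads may be assigned to one another and the value of each is uncertain. Over all samples Sowaha also lost the call without any 1 of lactating WT 1 to 6, 8 and 11, KO 1 and KO 2. Rfk lost it without lactating WT 2, 5 or 6, Cirbp without lactating WT 1, 3, 6 or 7, and the interferon-induced Xaf1 without lactating WT 4 (adjusted p 0.0505 to 0.0913). Within the version Mt1 lost it without virgin 1, virgin 2 or lactating WT 7, 9 or 11 (0.0624 to 0.152), and Gsdmc4 without virgin 2 (0.0554). Fgf15 lost it without virgin 2, virgin 3 or lactating WT 11 (0.0944, 0.0883 and 0.0608), and Psmb8 without virgin 1, virgin 2 or lactating WT 7, 8, 9 or 11 (0.0555 to 0.153). With clustering at resolution 0.5 and with centred genes the calls of Mt1 (0.0989 and 0.108), Gsdmc4 (0.0595 and 0.301), Fgf15 (0.101 and 0.171) and Psmb8 (0.0868 and 0.108) were lost within the version as well. For Flvcr2, Acaa1b, Aqp3, Gsdmc2, Abca1, Naip1 and Kitl the calls within the version were not examined under such alternatives or without single samples.

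In all, 43 of 11367 enterocyte genes passed over all samples, 30 higher and 13 lower in lactating WT (edgeR; 264 with DESeq2), and 207 of 12371 within the version, 125 higher and 82 lower, with 35 genes in both sets. Without virgin 1, 2 or 3 the count over all samples was 20, 3 and 3. Within the version it was 116, 28 and 91 without virgin 1, 2 or 3, 122, 136 and 116 without lactating WT 7, 8 or 11, and 28 with clustering at resolution 0.5 or with genes centred within samples.

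Of the list of calcium, phosphate, iron and zinc absorption, 24 genes were tested in enterocytes. Over all samples 2 rose and 0 fell, and adjusted over the list alone 6 rose and 5 fell. Within the version 3 rose (Slc30a10, Slc39a4, S100g) and 2 fell (the phosphate transporter Slc20a1, log2 -0.65, adjusted p = 0.0104, and Mt1), and adjusted over the list alone 6 rose and 4 fell. The list as a whole was not called by camera in either fit (adjusted p = 0.0583 and 0.2205; adjusted p = 0.567 and 0.75 with an estimated correlation). Of 21 genes of prolactin, STAT5 and RANK signalling, Cish (log2 0.72 ± 0.10, adjusted p = 0.0102) and Socs2 (0.51 ± 0.09, adjusted p = 0.0217), both feedback inhibitors of cytokine signalling, rose within the version and Bcl6 fell, and adjusted over the list alone 2 rose and 4 fell. Over all samples Cish rose (adjusted p = 0.02) and Socs2 did not pass (log2 0.34, adjusted p = 0.343), with 1 up and 4 down adjusted over the list alone. Cish lost the call within the version without virgin 2 (adjusted p = 0.0773), with clustering at resolution 0.5 (0.0646) and with centred genes (0.0889).

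Among 27 tested genes of peptide and amino acid absorption, 0 passed singly in edgeR, over all genes and adjusted over the list alone, in both fits. The genes with the smallest p were the peptidases Lap3 (log2 0.80 over all samples, 0.42 within the version), Ggt1 (0.64 and 0.39) and Dpp4 (0.73 and 0.23). The list was called higher by camera (adjusted p = 0.0150 over all samples and 0.0371 within the version; adjusted p = 0.567 and 0.75 with an estimated correlation), and lost the call over all samples without virgin 2 (0.0569) or virgin 3 (0.0958). Stem cell and Wnt target genes, 18 tested, were called lower (adjusted p = 0.00338 and 0.00881; adjusted p = 0.567 and 0.75 with an estimated correlation), with Sox9, a crypt transcription factor, at log2 -1.45 over all samples (not called) and -0.86 within the version (adjusted p = 0.0339). It was the 1 member called within the version, over all genes and adjusted over the list alone, and over all samples 0 were called either way. Unfolded protein and stress response genes, 23 tested, were called higher (adjusted p = 0.000204 and 0.0207; adjusted p = 0.567 and 0.75 with an estimated correlation). Their median log2 change was 0.56 over all samples and 0.15 within the version, and the smallest p belonged to Chac1, an enzyme that degrades glutathione (2.30 and 1.23). Adjusted over the list alone 0 members rose over all samples and 1 within the version. Ribosomal protein genes, 81 tested, were called lower as a list (adjusted p = 1.34e-05 and 0.00706; adjusted p = 0.629 and 0.75 with an estimated correlation), with median log2 changes of -0.28 and -0.14 and 0 genes called singly, over all genes or adjusted over the list alone.

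Lists of immune genes differed with the file version. Antimicrobial and barrier genes, 29 tested, had a median log2 change of 0.77 over all samples while camera gave the direction down (adjusted p = 0.944), and -0.50 within the version, where the list was called lower (adjusted p = 6.88e-07; adjusted p = 0.75 with an estimated correlation). There 4 genes fell, Saa3 and the gasdermins Gsdmc2, Gsdmc3 and Gsdmc4, and adjusted over the list alone 11 fell. Over all samples 1 fell, Gsdmc4, and adjusted over the list alone 1 rose and 4 fell. Interferon response genes, 43 tested, were called higher over all samples (adjusted p = 9.90e-10; adjusted p = 0.567 with an estimated correlation), with 1 gene up, Xaf1, and 5 adjusted over the list alone. Within the version the list was not called (adjusted p = 0.0679), Bst2 and Xaf1 rose and Psmb8 fell, and adjusted over the list alone 11 rose and 5 fell. The median log2 change of 9 MHC class II genes was 1.65 over all samples and -0.71 within the version, called in neither (adjusted p = 0.0506 and 0.4705).

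In crypt progenitors Slc30a10 rose from 0.104 CPM in virgin samples to 9.03 CPM (means, n = 3 and 5) in lactating WT samples of the same version, with edgeR adjusted p = 0.00425 (over all samples adjusted p = 0.000109). Virgin samples held 2 UMIs of it, with 2 of the 3 samples at 0, against 283 UMIs, a ratio of 86.0 with a 95% counting interval of 23.6 to 714. The fitted log2 change within the version ran from 5.58 to 8.69 without one sample. In lactating WT 7 to 11 the CPM of Slc30a10 in crypt progenitors was 8.15% to 26.9% of that in enterocytes. For 62 enterocyte markers the median of this ratio was 2.73% to 3.54%. No test of free enterocyte RNA was set for Slc30a10. Slc31a1 rose by 0.92 ± 0.12 (adjusted p = 0.00501; over all samples 0.88 ± 0.15, adjusted p = 0.0167), as did Fbln1, an extracellular matrix protein (0.80 ± 0.09, adjusted p = 0.00425; over all samples 0.82 ± 0.14, adjusted p = 0.0174), and the heparan sulfatase Sulf2 (1.24 ± 0.16, adjusted p = 0.00604; over all samples 1.82 ± 0.33, adjusted p = 0.0394). Socs2 rose from 147 ± 4.41 to 238 ± 9.45 CPM (SD, n = 3 and 5) within the version (log2 0.68 ± 0.07, adjusted p = 0.00425; over all samples 0.41, adjusted p = 0.575). Gsdmc3 and Gsdmc4 fell, by 2.15 and 1.98 on the log2 scale within the version (adjusted p = 0.0138 and 0.0168) and by 2.10 and 1.76 over all samples (adjusted p = 0.00215 and 0.00707). Within the version S100g (log2 2.39 ± 0.36, adjusted p = 0.0166), Slc39a4 (0.79), Rgcc (1.28), Acta1 (1.20) and Tspan13 (0.68) also rose, and Mt2 (-2.01), Gsdmc2, St3gal4 (-1.35), Ly6e (-0.97), Psmb8 (-0.94) and Apol10a (-0.90) were lower, with adjusted p from 0.00621 to 0.0496. Over all samples none of these 11 was called, and St3gal4, Ly6e, Psmb8 and Apol10a had positive changes of 0.53, 0.18, 1.90 and 2.05.

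In crypt progenitors, 7 of 10140 genes passed over all samples, 5 higher and 2 lower (edgeR; 16 with DESeq2), and 60 of 10792 within the version, 26 higher and 34 lower. Over all samples the count was 1 without virgin 1, 3 without virgin 2 and 4 without virgin 3. All 5 genes that the rule named there lost the call without virgin 1 (adjusted p 0.171 to 0.234), and Sulf2, Slc31a1 and Fbln1 lost it without virgin 2 (0.177 to 0.51) and without virgin 3 (0.0635 to 0.271). Sulf2 also lost it without any 1 of lactating WT 2 to 6 or KO 1 to 3 (0.0514 to 0.0802). Within the version the count was 17, 21 and 32 without virgin 1, 2 and 3, 14, 28, 31 and 26 without lactating WT 7, 8, 9 and 11, 6 with clustering at resolution 2, 22 with centred genes, 23 after thinning and 124 with no filter on low counts. There S100g lost the call without virgin 1 (0.0949) or virgin 3 (0.073). Slc39a4 lost it without virgin 1 (0.0949), virgin 2 (0.0869) or lactating WT 7 (0.0576), Gsdmc4 without virgin 1 (0.0949) or lactating WT 7 or 11 (0.0542 and 0.0508). With centred genes S100g (0.0755) and Slc39a4 (0.066) lost it, Slc39a4 also after thinning (0.0557), and at resolution 2 Slc39a4 (0.302) and Gsdmc4 (0.546). Slc30a10 and Socs2 kept it without any single sample. The unfolded protein and stress response list was called higher (adjusted p = 8.56e-09 over all samples and 5.25e-06 within the version; adjusted p = 0.473 and 0.419 with an estimated correlation). Of its 23 genes 0 passed singly in edgeR in either fit, and adjusted over the list alone 13 rose over all samples and 5 within the version, with Pdia4, a protein disulfide isomerase, at log2 1.45 and 0.48 and Sdf2l1 at 1.70 and 0.57. Within lactating WT, camera also called this list higher in version 5.0.1 than in 4.0.0 (adjusted p = 7.88e-06, and 0.108 with an estimated correlation). Its median log2 change there was 0.70, so the file version can add to its values over all samples. MHC class II genes were called lower within the version (9 tested, adjusted p = 0.00128; adjusted p = 0.419 with an estimated correlation; 0 over all genes and 8 adjusted over the list alone). Over all samples their median was 1.49 and they were not called (adjusted p = 0.1002).

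In goblet cells of lactating and virgin WT, 0 genes passed over all samples (edgeR; 226 at an unadjusted p under 0.05, 0 with DESeq2). S100g had a log2 change of 2.71 ± 0.37 within the version (SE; adjusted p = 0.106) and 2.12 over all samples, Ang4, a ribonuclease of secretory cells, -2.80 ± 0.59 (adjusted p = 0.465 over all samples) and Gsdmc4 -2.23 (adjusted p = 0.465). Without lactating WT 10 the count was 1. S phase genes, which copy DNA, were called lower as a list (40 tested; adjusted p = 4.23e-07 over all samples and 7.46e-08 within the version; adjusted p = 0.566 and 0.621 with an estimated correlation), with Mcm2 at log2 -0.47 and -0.34 and Mcm6 at -0.46 and -0.33. Microvillus genes were called higher (22 tested; adjusted p = 4.23e-07 and 0.00745; adjusted p = 0.566 and 0.742 with an estimated correlation), with Cdhr5 at 0.73 and 0.68 and Pls1 at 0.77 and 0.55. In both lists 0 members passed, over all genes or adjusted over the list alone.

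With all cells of a sample summed, Slc30a10 (log2 2.35 ± 0.34, SE), Slc39a4 (1.44 ± 0.26) and Eif4ebp3 (0.88 ± 0.14) were higher in lactating WT, and Gsdmc4 (-2.06 ± 0.33), Gsdmc2 (-1.91 ± 0.35) and Cirbp (-0.58 ± 0.11) were lower, with adjusted p from 0.00595 to 0.0419. In this sum 14 of 12349 genes passed, 10 higher and 4 lower (edgeR; 135 with DESeq2), and 34 within the version, where Eif4ebp3 and Cirbp were not called (adjusted p = 0.0754 and 0.112). There S100g (5.39), Angptl4 (1.92), Tgfbi (-0.72) and Tgm2 (-0.69) passed as well, with adjusted p from 0.00458 to 0.0466. The count over all samples was 2, 1 and 1 without virgin 1, 2 and 3, and all 6 genes named over all samples lost the call without any 1 of them. Cirbp also lost it without any 1 of lactating WT 1, 2, 3, 5, 6, 7 and 8, KO 1 and KO 3. Gsdmc2 lost it without any 1 of lactating WT 1, 2, 5, 6, 7, 8 and 11, and Slc39a4 without any 1 of lactating WT 2, 6, 7 and 8 and KO 3 (adjusted p 0.0519 to 0.0771). The count was 9, 6, 8 and 8 without lactating WT 1, 2, 5 and 6, 24 without lactating WT 9 and 9 without KO 3.

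The second question was what the loss of SGLT3a changes in lactation. Slc5a4a, the targeted gene (ENSMUSG00000020229; chromosome 10, 76147451 to 76189265), had 6, 4 and 2 UMIs in all kept cells of KO 1 to 3. Lactating WT 1 to 6 had 201, 160, 101, 200, 141 and 122 UMIs. Lactating WT 7 to 11 had 1372, 1117, 3020, 1200 and 264, and virgin 1 to 3 had 631, 421 and 58. In enterocytes it fell from 16.0 ± 4.87 CPM (SD, n = 6) in lactating WT samples of the same version to 0.465 ± 0.268 CPM (SD, n = 3) in KO samples, a log2 change of -5.12 ± 0.44 (SE; edgeR adjusted p = 0.000563; over all samples -5.60 ± 0.81, adjusted p = 0.00776). The labels do not say which part of the gene was deleted, so it is not known whether the counted 3' tags lie in it. The call over all samples was lost without KO 1, 2 or 3 (adjusted p = 0.0975, 0.138 and 0.22), and within the version it was kept without any single sample (at most 0.0067). In lactation against virgin, Slc5a4a had a log2 change of 1.52 ± 0.51 over all samples (adjusted p = 0.255) and 1.89 ± 0.55 within the version (adjusted p = 0.126), so it was not called.

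**Figure D3:**
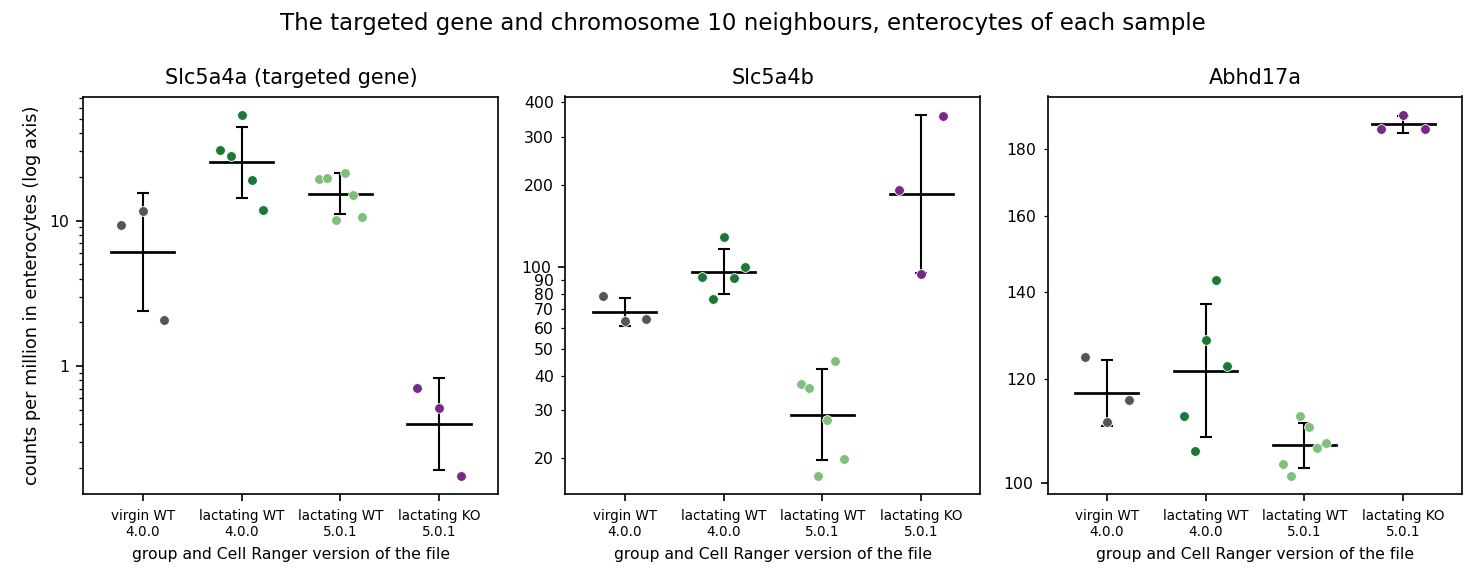
CPM of Slc5a4a, Slc5a4b and Abhd17a, all on chromosome 10, in enterocytes, on log axes, with 1 point per sample in 4 groups by condition and Cell Ranger version; black lines are geometric means and bars 1 SD of the log10 values either way. Slc5a4a averages 0.465 CPM in the KO samples and 16.0 CPM in the lactating WT samples of the same version.

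Of 160 other tested genes within 10 Mb of Slc5a4a on chromosome 10, Slc5a4b aside, Abhd17a alone passed within the version in KO enterocytes. Abhd17a, a depalmitoylating enzyme (ENSMUSG00000003346; 80583654 to 80590341), rose from 107 ± 4.23 CPM (SD, n = 6) in lactating WT samples of the same version to 188 ± 2.79 CPM (SD, n = 3) in KO samples, by 0.84 ± 0.10 on the log2 scale (SE; edgeR adjusted p = 0.00698; over all samples 0.74 ± 0.10, adjusted p = 0.00396). Over all samples its call was lost without KO 1 (adjusted p = 0.0512) or KO 2 (0.0519). Zfp280b, a zinc finger gene (ENSMUSG00000049764; 76032650 to 76043234), chosen after its values were seen because it fell under the expression level of the naming rule, rose by 1.34 ± 0.15 over all samples (4.13 to 10.3 CPM; adjusted p = 0.000476) and had a change of 1.31 ± 0.20 within the version (adjusted p = 0.0503). Slc5a4b, a paralog of Slc5a4a next to it (ENSMUSG00000020226; 76057494 to 76110961), had 30.6 ± 10.9 CPM (SD, n = 6) in lactating WT samples of the same version and 214 ± 132 CPM (SD, n = 3) in KO samples, with log2 2.84 ± 0.36 within the version (adjusted p = 0.0145) and 1.82 ± 0.47 over all samples (adjusted p = 0.791). It lost the call within the version without lactating WT 1 (0.0563), lactating WT 4 (0.057) or KO 3 (0.0545), and reads shared between the paralogs make the value of each uncertain.

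With the full set of samples of each fit, the enterocyte genes that passed in the knockout were Slc5a4a and the nearby Zfp280b, Abhd17a and Slc5a4b. In enterocytes 3 of 11367 genes passed over all samples, Zfp280b and Abhd17a higher and Slc5a4a lower (edgeR; 660 at an unadjusted p under 0.05). There were 3 of 10251 within the version, Abhd17a, Slc5a4b and Slc5a4a (16 with DESeq2). Over all samples the count was 1 without KO 1, 1 without KO 2 and 2 without KO 3. Within the version it was 80 without KO 2, 2 without KO 3, 2 without lactating WT 1 and 2 without lactating WT 4, and 17 with no filter on low counts. Slc5a1, the main glucose transporter of the gut (log2 0.23 over all samples, -0.07 within the version), and Slc2a5, the fructose transporter (0.39 in both), were not called. In all cells summed 3 genes passed, Zfp280b, Abhd17a (log2 0.68, adjusted p = 0.046) and Slc5a4a (-5.64 ± 0.89, adjusted p = 0.0384), and within the version 1, Slc5a4a (-5.16, adjusted p = 0.00909). Over all samples Zfp280b kept the call there without any single sample (0.000143 to 0.0186). Abhd17a lost it without any 1 of the samples except lactating WT 4, 9 and 10 (0.0659 to 0.635), and Slc5a4a without virgin 1, lactating WT 1, 2, 5, 7 or 8, or KO 1, 2 or 3 (0.0541 to 0.541), and without each of these the count was 1. In crypt progenitors 0 genes passed over all samples (edgeR; 775 at an unadjusted p under 0.05, 0 with DESeq2) and 0 within the version (306 at an unadjusted p under 0.05; 5 without KO 2, 1 without KO 3 and 33 with no filter on low counts). In goblet cells 0 passed (edgeR; 539 at an unadjusted p under 0.05, 0 with DESeq2), 4 without KO 2, and 1 without virgin 1, 2 or 3 and 1 with no filter on low counts. Fgfbp1, which marks upper crypt cells, was called in neither comparison of enterocytes (log2 -0.32 for lactation and -0.54 for the knockout) or of crypt progenitors (-0.28 and -0.16).

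Of the gene lists, those of the mitochondrial respiratory chain and of the ribosome were called higher in KO crypt progenitors in both fits. Chance could not be excluded for the number of lists called in this class, since 40 of 100 splits of all samples gave as many as the real 12. Oxidative phosphorylation genes, 78 tested, had a median log2 change of 0.24 over all samples and 0.16 within the version (adjusted p = 1.37e-06 and 8.23e-05; adjusted p = 0.732 and 0.836 with an estimated correlation). Ribosomal protein genes, 81 tested, had medians of 0.16 and 0.25 (adjusted p = 1.62e-06 and 1.73e-14; adjusted p = 0.732 and 0.836 with an estimated correlation). In KO goblet cells oxidative phosphorylation genes were called higher (adjusted p = 3.68e-10 and 5.48e-05; adjusted p = 0.589 and 0.838 with an estimated correlation), as were lipid absorption genes (24 tested; adjusted p = 9.28e-07 and 0.00469; adjusted p = 0.577 and 0.838 with an estimated correlation), with the fatty acid-binding protein gene Fabp1 at log2 2.85 and 2.27 and Apoa4 at 2.15 and 1.90. The lipid list lost its call over all samples without KO 1 (0.962). Goblet cells of KO 1 also had more of the enterocyte transcripts Slc39a4 (304 CPM, against 65.65 to 168.7 in lactating WT of the same version) and Slc5a1 (184 CPM, against 59.44 to 131.3), and free enterocyte RNA as the source of the lipid genes was not tested. Of all these members 0 passed singly over all genes. Adjusted over the list alone 9 lipid genes rose over all samples and 0 within the version, and 0 members of the other lists rose in either fit. Within lactating WT, camera also called both goblet lists higher in version 5.0.1 than in 4.0.0 (adjusted p = 0.000178 and 1.75e-05; 0.694 and 0.221 with an estimated correlation). In crypt progenitors it called oxidative phosphorylation genes higher (0.0418; 0.719 with an estimated correlation) and did not call ribosomal protein genes (0.258). In enterocytes 3 lists were called higher over all samples, interferon response, oxidative phosphorylation and microvillus genes (adjusted p = 0.00372, 1.40e-04 and 0.0116; adjusted p = 0.929 for each with an estimated correlation). Within lactating WT these 3 were also higher in version 5.0.1, that of all KO samples, than in 4.0.0 (adjusted p = 2.92e-08, 4.08e-06 and 3.83e-05; adjusted p = 0.488, 0.652 and 0.488 with an estimated correlation). Within the version 8 lists were called, none of them among those 3, and 0 with an estimated correlation. The unfolded protein and stress response list was one of the 8, lower within the version (adjusted p = 3.64e-06; adjusted p = 0.799 with an estimated correlation) and not called over all samples (adjusted p = 0.393), with 0 members called singly, over all genes or adjusted over the list alone.

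The third question was whether genes that changed in lactation moved back in the knockout. Both comparisons share the lactating WT samples with opposite sign, so these were split into odd and even numbers. Across 11367 enterocyte genes, which are not independent replicates, the log2 changes of the comparisons correlated at 0.307 (covariance 0.0529), and at 0.528 with odd and even exchanged, beside 0 in 20 simulations of unchanged groups. The file version, which differs between virgin and KO samples and is mixed in lactating WT, can move both comparisons in the same direction, and these simulations leave it out. Without the split the correlation was 0.405 (covariance 0.0754), beside -0.212 (covariance -0.0241) in the simulations. Within the versions, which share no samples, it was 0.142. With the split, without KO 1, 2 or 3, it was 0.054, 0.133 and 0.527. Of the genes called for lactation within the version, 176 were tested in the knockout comparison as well. Of these, 65 (36.9%) had the opposite direction there, beside 48.7% of all genes tested in both. These shares show no excess of opposite directions within the versions.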

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

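The comparison of enterocytes with crypt progenitors was made after the main results were seen, as were the tests of file version given here. The tests of free RNA were set before. The 33 genes compared had been named for their change in these same samples. Over all samples, 3 of them changed differently in enterocytes and crypt progenitors between virgin and lactating WT, by an exact permutation test over all splits (two-sided). Each of the 3 had p = 0.00275, the smallest that these splits can give, and adjusted p = 0.0302. The log2 change of S100g, with 2 CPM added, was larger in enterocytes by 3.27 (3.67 against 0.40). That of Mt1 differed by -2.06 (-3.49 against -1.43), and that of Fgf15 by -1.64 (-2.03 against -0.39). Within samples of 1 file version the differences were 3.21, -1.40 and -1.17, with adjusted p = 0.0537 each and p = 0.0179, the smallest that 56 splits can give. The same p was reached there by Angptl4 (1.83), Flvcr2 (1.36), St3gal4 (1.35), Aqp3 (1.2), Acaa1b (1.05), Slc39a4 (0.9), Acta1 (0.81) and Rgcc (-1.11). Within the version this test therefore does not set S100g, Mt1 and Fgf15 apart from those genes. The rule on single samples far from their group needs 4 to 10 samples and was not applied, since the groups hold 3 and 11.

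Within 1 file version S100g also rose in crypt progenitors of lactating WT (adjusted p = 0.0166; over all samples 0.59), and its log2 change in goblet cells was 2.71 but did not pass (adjusted p = 0.106). Free enterocyte RNA in these droplets would give S100g the same ratio to its enterocyte level as other enterocyte transcripts have. In crypt progenitors of lactating WT 7 to 11 the ratio of S100g was 3.34 to 7.82 times the median ratio of 62 enterocyte markers, which argues against free RNA as the whole source. The log2 change of 2.39 within that version argues against the file version. In goblet cells it was 1.55 to 2.27 times that median, too near it to decide, so free RNA and expression in goblet cells cannot be told apart. Expression of S100g in the crypt in lactation remains a hypothesis.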

How the results depend on the processing

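The fits within 1 Cell Ranger version and with the version as a covariate, and the alternatives run inside 1 version, were chosen after seeing the data. Other settings were planned. Of 268 counts, shares and correlations under alternatives other than leaving out one sample, 183 stayed within their limits, 61 moved and 24 reversed. Of 502 without one sample 420 stayed, 54 moved and 28 reversed. Of 1408 values of named genes under the same alternatives 1167 kept their side of the threshold, 78 lost the call, 129 gained it and 34 reversed. Of 1728 without one sample 1544 kept it, 172 lost it, 11 gained it and 1 reversed. Of 88 list values 37 kept their side, 47 lost the call, 2 gained it and 2 reversed. Of 374 without one sample these were 345, 18, 4 and 7. Where a value changed, the cause was not tested, except that thinning and the strict filter leave fewer counts, leaving out a sample leaves fewer samples, and dropping the count filter tests more genes. A share of epithelial cells alone gave no further value, since no immune or stromal class was found, and tests of single genes in other classes were not run.

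For lactation, enterocyte genes numbered 264 with DESeq2, 165 with a surrogate variable, 20 with the strict filter, 72 at resolution 2, 207 within a version and 108 with version as a covariate, and 3 (without virgin 2) to 61 (without lactating WT 10) without one sample. Within the version they were 502 with DESeq2, 28 at resolution 0.5, 312 at resolution 2, 28 with centred genes, and 28 (virgin 2) to 290 (lactating WT 10) without one sample. Crypt genes numbered 16 with DESeq2, 21 with a surrogate variable, 1 after thinning, 4 at resolution 2, 4 with centred genes, 60 within a version, 29 with the covariate, and 1 (virgin 1) to 9 (lactating WT 8) without one sample. Within the version they were 124 with no count filter, 23 after thinning, 6 at resolution 2, 22 with centred genes, and 14 (lactating WT 7) to 57 (lactating WT 10) without one sample. Goblet genes numbered 1 with a surrogate variable, after thinning and with doublets kept, and 0 to 1 (lactating WT 10) without one sample. In all cells they numbered 135 with DESeq2, 31 with a surrogate variable, 34 within a version, 32 with the covariate, and 1 (virgin 2) to 24 (lactating WT 9) without one sample.

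For the knockout, enterocyte genes numbered 8 with the covariate and 1 (KO 1) to 3 without one sample. Within the version they were 16 with DESeq2, 17 with no count filter and 2 to 80 (KO 2) without one sample. Crypt genes within the version numbered 33 with no count filter and 0 to 5 (KO 2) without one sample. Goblet genes numbered 1 with no count filter and 0 to 4 (KO 2) without one sample. In all cells they numbered 1 with the strict filter and within a version, 7 with the covariate, and 1 to 3 without one sample. Slc5a4a in all cells lost its call with a surrogate variable (-5.56) and with the strict filter (-5.59), and its range without one sample was -6.15 to -5.23, and -6.07 to -5.11 in enterocytes.

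With an estimated correlation 0 lists were called in each class and comparison, and with fry 1 in enterocytes for lactation and 0 elsewhere. Within a version lists numbered 8 in enterocytes, 6 in crypt progenitors and 8 in goblet cells for the knockout, and 5 in crypt progenitors for lactation. Without one sample they were 1 (KO 2) to 4, 2 (KO 1) to 19 (KO 3) and 6 (KO 1) to 15 in these classes for the knockout. Adjusted p without one sample, where a direction turned, ran from 0.509 to 0.997 for antimicrobial genes in lactation and from 8.03e-11 to 0.962 (KO 1) for lipid absorption in KO goblet cells. The reversal correlation was 0.528 with odd and even numbers exchanged, 0.142 within versions, and 0.054 (KO 1) to 0.527 (KO 3) without one sample.

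None of the share or cycling differences passed under any setting. For lactation, in percentage points, enterocytes turned to 0.58 (strict filter) and 0.36 (at least 2000 UMIs), with -1.4 to 0.23 without one sample, crypt progenitors to 0.02 (doublets kept), 1.61 (resolution 2) and 2.95 (centred genes), with -0.66 to 0.38, and enteroendocrine cells to 0.09 (1 version), with -0.16 to 0.05. For the knockout, enterocytes turned to 1.02 (strict filter), 0.23 (resolution 2) and 1.2 (centred genes), with -2.2 to 2.56, crypt progenitors to 0.31 (strict filter), 0.3 (resolution 0.5), 0.23 (centred genes) and 0.51 (at least 2000 UMIs), with -2.45 to 1.09, goblet cells to -0.91 (strict filter), with -0.37 to 1.27, Paneth cells to 0.01 (at least 2000 UMIs), with -0.22 to 0.07, and enteroendocrine cells to 0.01 (1 version). Within a version the S phase and G2 and M phase scores turned to 0.11 and 0.48 for lactation and 0.41 and 0.38 for the knockout. The knockout difference in cycling share turned to 0.82 (strict filter) and 3.05 (1 version), with -6.93 to 4.88 without one sample, and -1.99 to 0.16 for the G2 and M phase score.

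Log2 changes that turned in enterocytes for lactation were those of Psmb8 (-0.94 with a surrogate variable, -0.94 within a version, -0.95 with the covariate) and Slc5a4b (0.49, 0.52, 0.51, and 0.01 with centred genes; in all cells 0.43, 0.55, 0.55, and -0.36 to 0.04 without one sample). In crypt progenitors, under the same 3 settings, they were St3gal4 (-0.89, -1.35, -1.34), Ly6e (-0.61, -0.97, -0.95, and -0.04 after thinning), Psmb8 (-0.32, -0.94, -0.93) and Apol10a (-0.21, -0.90, -0.89). For the knockout they were Slc5a1 in enterocytes (-0.07 within a version, -0.09 with the covariate) and Fgfbp1 in crypt progenitors (0.07 and 0.06).

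The sample numbers do not pair the samples: of 9 pairs of equal number, correlations ran from -0.57 to 0.47 and 4 correlated best with their own number. The fits with the number as a block hold only samples 1 to 3 of each group, so for lactation they set virgin samples of version 4.0.0 against lactating WT samples of 5.0.1, and the file version enters every difference. With the number as a block, lactation gave 3264 genes in enterocytes, 2248 in crypt progenitors, 193 in goblet cells and 2256 in all cells, and the knockout 1 in enterocytes and 1 in all cells, with 6 lists in enterocytes. With the block, log2 changes for lactation turned for Acaa1b (-1.21), Aqp3 (-1.36) and Naip1 (0.37) in enterocytes, S100g (-0.73) and Rgcc (-1.25) in crypt progenitors and Tgm2 (0.21) in all cells, and for the knockout for Fgfbp1 (0.11) in crypt progenitors. List directions turned with the block for antimicrobial genes of enterocytes (adjusted p = 0.0888) and G2 and M phase genes of goblet cells (0.825) in lactation. Shares turned with the block for crypt progenitors in lactation (2.36) and enterocytes in the knockout (2.23), where the smallest p that 3 pairs allow is 0.25.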

Other observations

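The tests of Slc5a4b reported here, and those of depth and of a wrong label for KO 3, were chosen after the result was seen. The splits and the test of immune cells were set before their own results were seen. The splits within a version still followed the finding of the file version, and the test of immune cells concerns a pattern found in the data. Within 1 file version, the genes called in enterocytes and in crypt progenitors for lactation overlapped. Of 10486 genes tested in both, 72 and 26 rose and 13 were shared, and 64 and 33 fell and 7 were shared. Both classes come from the same samples, so some overlap arises without a shared response, and it was not tested. The shared rises include the metal transporters Slc30a10, Slc39a4 and Slc31a1, S100g, Socs2 and the riboflavin transporter Slc52a2. The shared falls include Gsdmc2, Gsdmc3, Gsdmc4, Psmb8 and Ly6e.

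Within 1 file version Slc5a4b was higher in KO enterocytes, a call lost without KO 3 or without lactating WT 1 or 4. Over all samples it was not called. If reads of Slc5a4a had only moved to Slc5a4b, the sum of both genes would not rise, but within 1 file version the log2 ratio of the summed CPM was 2.2. The change of Slc5a4b of 2.84 there argues against the version named in the headers, and it stayed at 2.25 to 3.2 without any single sample. However, 96.33% of the crypt progenitors of KO 3 lay in the cluster of version 4.0.0. For KO 3 the fit therefore does not exclude whatever else sets the versions apart. A candidate explanation is a segment of chromosome 10 carried along with the targeted allele: of the 20 genes with the smallest p in that comparison, 2 (Abhd17a and Zfp280b) lie within 10 Mb of Slc5a4a. Both had already been called, so this count restates what was seen and the segment stays open. An effect of the deletion itself on its neighbours was not tested and stays open.

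Enterocytes of KO 3 had 2930 CPM of MHC class II transcripts, beside 6436 to 8307 CPM in the 6 lactating WT samples of the same version, and were also low in Reg3b with Reg3g (14820 CPM, against 41540 to 161800 CPM in the other 8 samples of the version), Saa1 (11.33 against 223.8 to 1654), Nos2 (19.18 against 102.2 to 201.6) and Ubd (2.092 against 69.8 to 279.3). Its depth of 15.02 M UMIs lies within that of the others, which argues against depth, and Slc5a4a was at 0.158 CPM in all its cells, under the lowest WT sample at 1.58 CPM, which argues against a WT library with a wrong label. The 6 transcripts Cd79a, Cd79b, Ms4a1, Lyz2, C1qa and Csf1r of B cells and myeloid cells together came to at most 0.0288% of Cd74 in the other samples, which argues against B cells and myeloid cells in those as the source. Summed markers of T cells (26.59 CPM in KO 3, 80.16 to 132.5 CPM in the other 8) and of B and plasma cells (19.53 CPM, against 38.2 to 95.01) were lower in KO 3 too, as was the myeloid sum (668.3 CPM, against 685.3 to 896.3), which was 629.7 to 749 CPM in lactating WT of version 4.0.0, where Cd74 was at 84.78 to 688.2 CPM. The myeloid list shares Ctss and Ifi30 with the list of MHC class II genes. The T cell list holds AW112010, which was called lower in lactating WT within version 4.0.0 in both enterocytes and crypt progenitors. These sums therefore need not follow immune cells alone. Fewer lymphocytes in KO 3 and a separate origin of the library stay open, and no biological explanation was tested.

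Other splits of the samples were tested the same way as the real one. The numbers of splits given for genes and for lists include the real split itself. For lactation over all samples, 1 of 100 splits gave as many genes in enterocytes (real 43, highest other 3). It was 2 of 100 in crypt progenitors (real 7, highest other 402, for lactating WT 1, 3 and 5, all of version 5.0.1) and 1 of 100 in all cells (real 14, highest other 0). These shares of splits are small, which argues against chance for the counts in enterocytes and in all cells. Within the version it was 1 of 56 in enterocytes (real 207, highest other 20), which argues against chance there too. It was 2 of 56 in crypt progenitors (real 60, highest other 119, for virgin 3 and lactating WT 10 and 11). In crypt progenitors another split thus called more genes than the real one in both fits, so a grouping other than lactation can give such a count. These shares were not adjusted for the number of counts tested. For the knockout, 6 of 100 splits gave as many genes in enterocytes (real 3, highest other 1319, for lactating WT 8, 9 and 11, all of version 4.0.0), so chance cannot be excluded. Within the version 2 of 84 did (real 3, highest other 50, for lactating WT 4 with KO 1 and 3), and in all cells 3 of 100 did (real 3, highest other 1145, for lactating WT 4 and 5 and KO 1, all of version 5.0.1). These shares are small, but each real count includes Slc5a4a, the targeted gene. They therefore do not exclude chance for the other genes called. With a real count of 0 every split gives as many: 100 of 100 in crypt progenitors for the knockout (edgeR, highest other 859, for lactating WT 7, 8 and 9, of version 4.0.0), and 84 of 84 there within the version (highest other 89). It was 100 of 100 in goblet cells for lactation (highest other 28) and 100 of 100 for the knockout (highest other 735). Splits that call many more genes than the real one point to a structure of the samples that the groups do not describe. Those of lactating WT 1, 3 and 5, of 8, 9 and 11, of 7, 8 and 9, and of lactating WT 4 and 5 with KO 1 put 3 samples of 1 file version together, whereas those in goblet cells, for lactation (lactating WT 1, 9 and 11) and for the knockout (lactating WT 9 and 11 with KO 1), mix versions.

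For lists, chance could not be excluded in any class. In enterocytes 31 of 100 splits gave as many lists for lactation (real 10, highest other 15) and 94 of 100 for the knockout (real 3, highest other 15). In crypt progenitors these were 29 of 100 (real 11, highest other 18) and 40 of 100 (real 12, highest other 20), and in goblet cells 7 of 100 (real 15, highest other 18) and 26 of 100 (real 13, highest other 18).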
